A study of Eisenia fetida with 15 samples.

How the data were processed

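The material is *Eisenia fetida*, a compost earthworm used in soil toxicity tests, and lindane, an organochlorine insecticide that blocks ligand-gated chloride channels of nerve cells. Per the labels, adult worms were kept in soil with a nominal 2.4 mg/kg lindane that was either freshly spiked or left to age for 30 d before the worms were added, and were taken after 7 d or 28 d. Total RNA came from sections of the whole body, was extracted with RNAiso Plus, cleaned, treated with DNase and checked on a Bioanalyzer, and was sequenced on Illumina instruments, per the labels' protocols. The 15 libraries form 5 triplets of 3.

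The labels give each triplet 2 different names. A code of the form soil aging, then exposure (0d-7d, 0d-28d, 30d-7d, 30d-28d, or control) stands in the description, the column header and, in brackets, the title of each library. The treatment text, the source name and the words of the same title name another condition, displaced by one triplet. The libraries coded 0d-7d are called 0 d of exposure in the treatment text, those coded 0d-28d are called 7 d in soil aged 0 d, those coded 30d-7d are called 28 d in soil aged 0 d, those coded 30d-28d are called 7 d in soil aged 30 d, and those coded control are called 28 d in soil aged 30 d. Both namings put the same 3 libraries together, so the spread within a triplet and the test of any difference do not depend on the choice. Groups are named by code here, all 10 pairwise contrasts were computed so that either naming can be followed, and the values were not used to choose between the namings.

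One deposited table holds 241846 unigenes, which are contigs of a de novo assembly per the series title. The authors deposited for each unigene and library a whole-number count of reads and an FPKM value, fragments scaled by unigene length and library size, per the file headers. The assembler, the aligner and the counting program are not given in the sources used here, nor is the treatment of reads that match several unigenes, so near-identical contigs of a gene are read as uncertain. FPKM was 0 exactly where the count was 0. All columns of per-sample values were used. Unigene lengths ran from 399 to 326896 bases with a median of 660 bases. The table gives 58313 unigenes a best protein match and 14584 of these a name other than uncharacterized or hypothetical. Names are taken from that column, and the matched protein is often from another phylum. No genome was used, so no chromosomal position is given for any unigene.

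Counts were tested as deposited with edgeR 4.0.16, quasi-likelihood F tests after filterByExpr (minimum count 10, minimum total count 15) and TMM scaling, in one fit of 5 triplets over all 15 libraries. The filter kept 101090 unigenes, of which 39706 had a protein match and 9379 an informative name. The fit had 10 residual degrees of freedom, a common biological coefficient of variation of 0.923 and a median prior of 2.46 degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The design written before the data were examined named limma on log2(FPKM + 1) for a table without counts and edgeR for a table with counts, and the table held counts. Log2 changes come from the edgeR fit and standard errors were taken as the change divided by the square root of the F statistic. FPKM means are given ± SD over 3 libraries. The labels do not say whether the libraries of a triplet came from separate worms, so p-values measure only the spread between these libraries. Repeat libraries of the same RNA would resemble each other most. Spearman's rho averaged 0.663 within triplets and 0.681 between them, which argues against such repeats. Whether the spread lies between worms or between body parts is not known.

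Before the data were examined, 25 gene lists were fixed as patterns on protein names, among them detoxification, antioxidant, neurotransmission, immune, digestive, muscle, globin, germ cell, gregarine and bacterial lists. The 23 lists with at least 5 tested unigenes were tested with camera at a preset correlation of 0.01 in 8 contrasts, 184 tests in 1 family, with camera at an estimated correlation and fry beside it. The list of ligand-gated chloride channels held 3 tested unigenes and that of gregarines 1, and neither was tested. Named unigenes were to be those past the threshold with triplets that do not overlap, a mean of at least 5 FPKM in the higher triplet and an informative name, the 6 largest rises and 6 largest falls per comparison with control and 4 and 4 in other contrasts, plus up to 2 changed members of each list. No unigene met that rule. The unigenes named below are therefore the 1 past the threshold, the most abundant members of each list, those with the lowest unadjusted p among informative names with separate triplets, list members that passed when adjusted over their list alone, unigenes called by limma, and the mitochondrial, long and set-specific unigenes of the closing section, all chosen after their values were seen.

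The edgeR, camera, limma and DESeq2 steps were tested on simulated data for the comparison of 0d-7d with control, with counts for all 101090 unigenes drawn from the measured means, library sizes and dispersions. edgeR recovered 0 of 67 unigenes changed 4 fold, 6 of 67 changed 16 fold and 31 of 66 changed 64 fold, with 0 false calls. limma on log2 values recovered 1, 21 and 37 of them with 13 false calls. DESeq2 recovered 17, 45 and 60 of them with 360 false calls. Camera called a list of 49 unigenes raised 2 fold at an adjusted p of 9.30e-06 and 0 other lists. The draws were independent between unigenes, whereas members of the real phase I detoxification list had a mean correlation of 0.257 across libraries. The simulation therefore does not show how often camera calls correlated lists falsely. At this spread edgeR missed most changes of 16 fold and over 0.5 of those of 64 fold with 3 libraries per triplet.

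Alternatives written before the data were examined were other filters, DESeq2 1.42.0 and its size factors, the replicate number as a block, fits of only the libraries compared, a minimum log2 change of 1, the treatment-field naming, each library left out in turn, and limma 3.58.1 on log2(FPKM + 0.1), on FPKM scaled by TMM-type factors or quantiles, without a trend or with array weights. Chosen after seeing the data were limma on log2(FPKM + 1), a filter on FPKM of at least 1 in 3 libraries, 2, 3 or 4 surrogate variables from sva 3.50.0, reads summed by matched protein, and DESeq2 on random splits. Distances between libraries were 1 minus Spearman's rho of log2 CPM with a prior count of 2, tested with vegan 2.7.1.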

Results

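RNA of the earthworm *Eisenia fetida* was sequenced from 15 libraries of body sections, 3 for each of 5 conditions of a lindane soil test with a nominal 2.4 mg/kg. The libraries held between 13182058 and 28022746 reads counted on 241846 unigenes, and the 101090 unigenes tested took 90.8% of the reads of 0d-28d library 3 and at least 97.8% in each other library. Codes give soil aging and then exposure, so that 30d-7d stands for soil aged 30 d and 7 d of exposure. The treatment text of the same libraries names a condition displaced by one triplet, under which the libraries coded control would be worms kept 28 d in soil aged 30 d and those coded 0d-7d would be the worms at 0 d. Each comparison below is therefore between triplets as coded, and a direction relative to control holds only if the code is right.

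Several abundant transcripts of known function differed more between libraries of 1 triplet than between triplet means. Lumbrokinase-7T1 (contig_150), a fibrinolytic gut protease, had 17735 and 11757 FPKM in 0d-28d libraries 1 and 2 and 4.02 FPKM in library 3. In the control triplet it had 1.51, 699.8 and 66.4 FPKM. Chitinase (contig_57366) stood at 8137 FPKM in control library 2 and at 0.702 and 0.355 FPKM in control libraries 1 and 3. Hemoglobin chain d1 (contig_842), a part of the extracellular oxygen carrier, ranged from 5.24 FPKM in 0d-28d library 3 to 8014 FPKM in 0d-7d library 3. PIWI1 (First_Contig345), a germ line protein, had 288.5 FPKM in 0d-28d library 3 and at most 5.79 FPKM in each of the 14 other libraries. Digestive enzymes as a list took 0.271% to 8.03% of the reads of a library, muscle contractile proteins 0.338% to 2.19%, globins 0.00322% to 2.03% and germ cell and sperm proteins 0.0279% to 0.572%. Spearman's rho between libraries averaged 0.663 within triplets and 0.681 between triplets across unigenes, and 1 of 15 libraries had its closest library in its own triplet. Triplets accounted for 21.8% of the variance in distance (permutation p = 0.984, vegan).

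**Figure D1:**
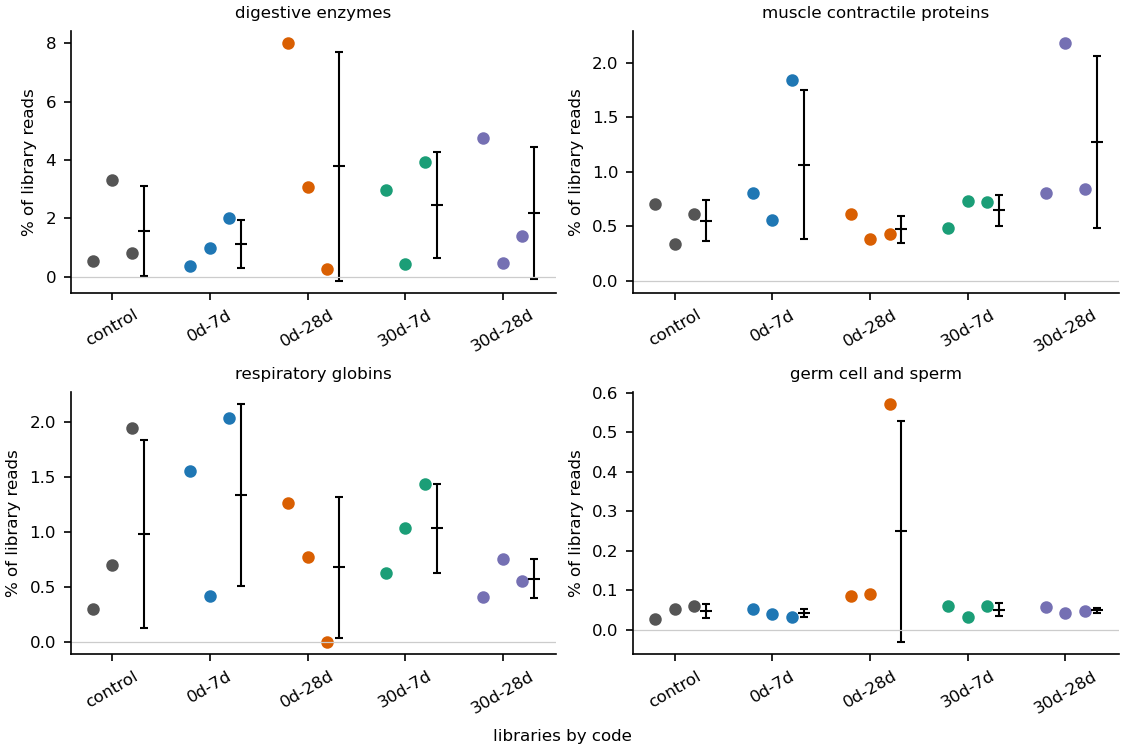
Share of each library's reads (%, vertical axes) taken by 4 gene lists, with libraries grouped by code. Points are single libraries, bars to the right of them are means ± SD (n = 3), and 0d-28d library 3 lies lowest for digestive enzymes (0.271%) and globins (0.00322%) and highest for germ cell and sperm proteins (0.572%).

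Across the 5 triplets 1 unigene changed, contig_17698, which is 4802 bases long and has no protein match (edgeR F test, adjusted p = 0.000261). This result does not depend on which label is right. It had 11.8 ± 5.51 FPKM in the control triplet (SD, n = 3), 0.579 ± 0.223 in 0d-7d, 0.321 ± 0.0359 in 0d-28d, 0.284 ± 0.0375 in 30d-7d and 0.313 ± 0.0502 in 30d-28d. In reads, the control libraries held 2856, 832 and 923 and the 12 others 18 to 59. At an unadjusted edgeR p under 0.05 there were 6134 unigenes where chance gives 5054.5, and a DESeq2 likelihood ratio test called 1042. The list of ligand-gated chloride channels, the class that lindane blocks, held only 3 tested unigenes, all of them GABA receptor-associated proteins, which are trafficking and autophagy proteins and not channels. The most abundant of them, contig_11568, had 191.4 ± 70.0 FPKM in control and 103.9 ± 36.6, 174.1 ± 118.1, 183.9 ± 81.9 and 271.4 ± 168.9 FPKM in 0d-7d, 0d-28d, 30d-7d and 30d-28d (SD, n = 3).

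**Figure D2:**
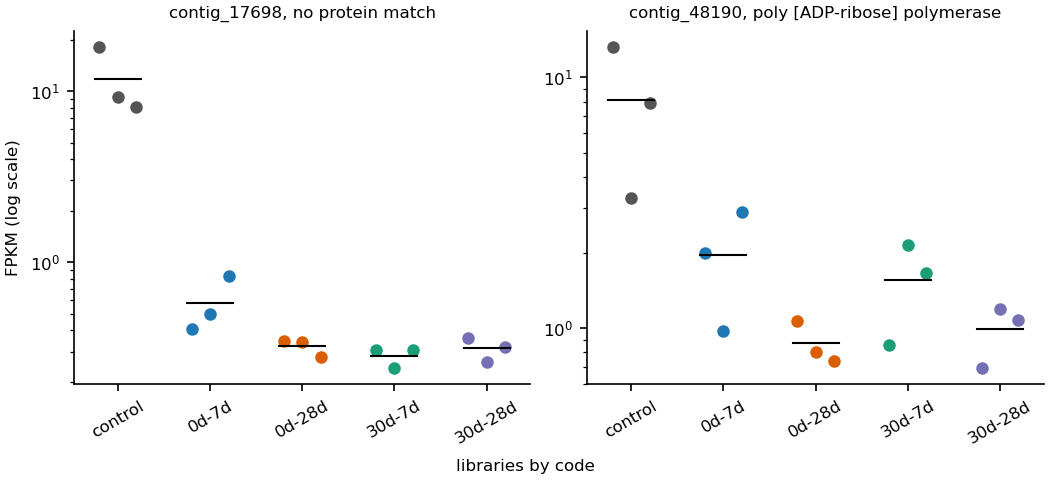
FPKM (log scale, vertical axes) of contig_17698 and contig_48190 in the 15 libraries grouped by code. contig_48190 is only one of the unigenes named poly [ADP-ribose] polymerase. Points are libraries and lines are triplet means, and the control libraries lie at 8.09 to 18.1 FPKM for contig_17698 and at 3.29 to 13.2 FPKM for contig_48190, above the 12 others in both.

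By the code, 0d-7d against control asks what 7 d in freshly spiked soil does. The code gives the control triplet no soil aging and no exposure time. In this and the following comparisons with control, lindane can therefore not be told apart from time in the soil or from soil aging. contig_17698 fell by 4.36 on the log2 scale (SE 0.424, edgeR adjusted p = 0.0189). Phase I detoxification enzymes, the oxidases and hydrolases that act first on foreign compounds, rose as a list, with 41 of 49 unigenes at a positive log2 change and a median of 0.95 (camera adjusted p = 1.01e-05, and adjusted p = 0.868 with an estimated correlation). Its most abundant members gave -1.15 (SE 1.08) for a flavin-containing dimethylaniline monooxygenase (contig_14224), 0.22 (SE 0.390) for NADPH--cytochrome P450 reductase (contig_4776) and 0.75 (SE 0.453) for aldehyde dehydrogenase (contig_3927). Muscle contractile proteins rose by a median of 0.41 with 60 of 88 positive (camera adjusted p = 0.00998), and glycolysis and TCA cycle enzymes by a median of 0.39 with 48 of 66 positive (camera adjusted p = 0.0282). Both had an adjusted p = 0.868 with an estimated correlation. At the preset correlation the highest adjusted p without 1 library was 0.0756 for phase I (control library 1), 0.131 for muscle (0d-7d library 2) and 0.358 for glycolysis (control library 3). Myosin contig_592 stood at 269.1 ± 266.5 against 113.6 ± 60.9 FPKM and glyceraldehyde-3-phosphate dehydrogenase contig_33542 at 619.3 ± 686.1 against 193.3 ± 99.9 FPKM (SD, n = 3). Poly [ADP-ribose] polymerase contig_48190, an enzyme of DNA damage repair, gave -2.08 (SE 0.561, edgeR adjusted p = 1). It was chosen for its low p, and other unigenes of that name did not follow it. contig_34051 gave 2.46 (SE 1.32), contig_56237 gave -0.08 (SE 1.32) and contig_13621 gave 0.05 (SE 0.348). At the unadjusted level 4796 unigenes had an unadjusted p under 0.05 where chance gives 5054.5, DESeq2 called 336, and triplets did not overlap for 8.49% of unigenes where chance gives 10%.

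By the code, 0d-28d against control asks what 28 d in freshly spiked soil does. contig_17698 fell by 5.13 on the log2 scale (SE 0.440, edgeR adjusted p = 0.00469). Germ cell and sperm proteins rose, with 53 of 64 positive and a median of 1.31 (camera adjusted p = 7.18e-07, and adjusted p = 0.649 with an estimated correlation). PIWI1 and the axonemal dynein heavy chain First_Contig6505 gave 5.13 (SE 1.80) and 2.02 (SE 0.747). The dynein stood at 6.90 ± 2.53 against 1.94 ± 1.49 FPKM (SD, n = 3), and without 0d-28d library 3 the list median was 0.37 with a camera adjusted p = 0.0129. Globins fell, with 3 of 23 positive and a median of -0.56 (camera adjusted p = 0.00237, and adjusted p = 0.868 with an estimated correlation), and without 0d-28d library 3 their adjusted p was 0.556. Phase I detoxification enzymes rose with 42 of 49 positive and a median of 0.73 (camera adjusted p = 0.00168), neurotransmission proteins with 63 of 85 and 0.51 (adjusted p = 0.00234) and digestive enzymes with 132 of 214 and 0.42 (adjusted p = 0.0341). The estimated correlation gave them adjusted p = 0.868, 0.649 and 0.868, and leaving out control library 1 gave phase I an adjusted p = 0.176 and leaving out 0d-28d library 1 gave digestive enzymes 0.449. DNA repair and apoptosis proteins fell, with 79 of 198 positive and a median of -0.25 (camera adjusted p = 0.0371, adjusted p = 0.868 with an estimated correlation, and 0.286 at the preset one without 0d-28d library 2). Poly [ADP-ribose] polymerase contig_48190 in that list gave -3.21 (SE 0.588) and passed when adjusted over the list alone (edgeR adjusted p = 0.0255) but not over all unigenes (adjusted p = 0.591). In all 8438 unigenes had an unadjusted edgeR p under 0.05, DESeq2 called 912, and 10.8% did not overlap where chance gives 10%.

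By the code, 30d-7d against control asks what 7 d in soil aged 30 d does. contig_17698 fell by 5.38 on the log2 scale (SE 0.446, edgeR adjusted p = 0.00309). Digestive enzymes rose with 131 of 214 positive and a median of 0.23 (camera adjusted p = 0.00956), muscle contractile proteins with 57 of 88 and 0.32 (adjusted p = 0.0358) and mitochondrial respiratory chain proteins with 31 of 49 and 0.16 (adjusted p = 0.00536). DNA repair and apoptosis proteins fell with 64 of 198 positive and a median of -0.33 (camera adjusted p = 0.0227). For all 4 lists the adjusted p was 0.868 with an estimated correlation. Without 30d-7d library 3 the digestive list had an adjusted p of 0.367 and muscle 0.248, while without 30d-7d library 1 DNA repair had 0.416 and without control library 3 the respiratory chain had 0.150. Bacterial proteins rose with 8 of 8 positive and a median of 0.69 (camera adjusted p = 0.000867, and adjusted p = 0.649 with an estimated correlation), and 2 of its members, contig_41956 and contig_55734, are unigenes of 235955 and 68634 bases. Poly [ADP-ribose] polymerase contig_48190 gave -2.37 (SE 0.567, edgeR adjusted p = 1), with 1.55 ± 0.647 against 8.15 ± 4.97 FPKM (SD, n = 3). Of the same name, contig_34051 gave -0.97 (SE 1.26), contig_56237 gave -0.73 (SE 1.33) and contig_13621 gave -0.11 (SE 0.348). In all 3537 unigenes had an unadjusted p under 0.05, DESeq2 called 316, and 7.32% did not overlap where chance gives 10%.

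By the code, 30d-28d against control asks what 28 d in soil aged 30 d does. contig_17698 fell by 5.22 on the log2 scale (SE 0.442, edgeR adjusted p = 0.00393). Muscle contractile proteins rose with 65 of 88 positive and a median of 0.62 (camera adjusted p = 4.70e-06, and adjusted p = 0.649 with an estimated correlation). Myosin contig_592 gave 2.03 (SE 0.857) and tropomyosin contig_2234, which controls myosin access to actin, gave 1.40 (SE 0.758), with 658.7 ± 493.5 against 276.0 ± 114.4 FPKM for the latter (SD, n = 3). Neurotransmission proteins rose with 61 of 85 positive and a median of 0.33 (camera adjusted p = 0.000618), phase I enzymes with 37 of 49 and 0.45 (adjusted p = 0.000697), digestive enzymes with 146 of 214 and 0.52 (adjusted p = 0.00436) and bacterial proteins with 8 of 8 and 0.89 (adjusted p = 0.00896). Their adjusted p with an estimated correlation was 0.649, 0.868, 0.868 and 0.729. Collagen and extracellular matrix proteins and glycolysis and TCA cycle enzymes rose by medians of 0.27 and 0.11 (camera adjusted p = 0.0371 and 0.0415), and DNA repair and apoptosis proteins fell with a median of -0.38 (adjusted p = 0.0146). Their adjusted p with an estimated correlation was 0.729, 0.868 and 0.868. Without control library 1 phase I had a preset adjusted p = 0.219, without control library 3 glycolysis had 0.419 and without 30d-28d library 3 collagen had 0.231. Without 30d-28d library 1 digestive enzymes had 0.423, bacterial proteins 0.0820 and DNA repair 0.312. Poly [ADP-ribose] polymerase contig_48190 gave -3.06 (SE 0.584) and passed when adjusted over the list alone (edgeR adjusted p = 0.0359) but not over all unigenes (adjusted p = 1). Of the same name, contig_34051 gave 0.27 (SE 1.25), contig_56237 gave -1.36 (SE 1.35) and contig_13621 gave -0.14 (SE 0.348). In all 4353 unigenes had an unadjusted p under 0.05, DESeq2 called 408, and 9.29% did not overlap where chance gives 10%.

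In all 4 comparisons with control contig_17698 was the 1 unigene changed, and it was lower each time. This held without control library 1 or 3, but in the 13 other fits without 1 library, whichever it was, 0 unigenes changed the same way in all 4 by edgeR. The number changed moved in 12 of 15 such fits for 0d-7d, 3 for 0d-28d, 3 for 30d-7d and 4 for 30d-28d. Without 1 of the libraries compared, the log2 change of contig_17698 was -5.60 to -3.90. DESeq2 on all libraries called 58 the same way in all 4. In 8 simulations of 5 unchanged triplets, with 1 simulated control triplet serving all 4 comparisons, the highest count changed the same way in all 4 was 0. The simulated counts, those of control included, were drawn independently for each unigene and library. They do not carry the sets of libraries that share high unigenes in the real data. That 0 therefore does not decide on chance for contig_17698. Over 11 other settings contig_17698 passed in 5 for 0d-7d, 8 for 0d-28d, 7 for 30d-7d and 7 for 30d-28d, with highest adjusted p of 0.171, 0.0727, 0.0915 and 0.114. Antioxidant enzymes, coelomocyte and immune proteins and phase II conjugating enzymes passed in no contrast, with lowest camera adjusted p of 0.263, 0.0555 and 0.343. The same holds for metallothioneins (0.0999), lipid metabolism (0.0555), DNA replication (0.0757), reproductive hormones and yolk (0.138) and mobile elements (0.263). Glutathione peroxidase contig_1215 had 1135 ± 611.7 FPKM in control and 1239 ± 297.8, 1314 ± 1173, 1277 ± 683.3 and 1517 ± 128.6 in the other triplets, and catalase contig_1132 had 85.6 ± 43.7 FPKM in control and 119.4 ± 23.5 to 151.9 ± 96.7 in the others (SD, n = 3). Heat shock protein 70 contig_645, a chaperone, had 445.0 ± 156.8 FPKM in control and 395.2 ± 149.5 to 494.7 ± 46.2 in the others. The gregarine list, for protozoan parasites common in earthworms, held 1 tested unigene, contig_16999, with 12.8 ± 13.4 FPKM in control and 11.2 ± 9.24 to 22.7 ± 6.77 in the others.

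Soil aging by the code at 7 d of exposure is 30d-7d against 0d-7d. Heat shock proteins and chaperones rose with 26 of 36 positive and a median of 0.41 (camera adjusted p = 0.00428), digestive enzymes with 145 of 214 and 0.46 (adjusted p = 0.00510) and cytosolic ribosomal proteins with 35 of 45 and 0.23 (adjusted p = 0.0369). Phase I detoxification enzymes fell with 13 of 49 positive and a median of -0.56 (camera adjusted p = 0.0235). The adjusted p with an estimated correlation was 0.868 for the first 3 lists and 0.895 for phase I. Heat shock protein 70 contig_645 gave 0.40 (SE 0.415) and ribosomal protein S6 contig_83 gave 0.46 (SE 0.270). Cathepsin C contig_650, a lysosomal peptidase chosen for its low p, gave 1.09 (SE 0.310). Without 0d-7d library 2 the phase I median was 0.04 (adjusted p = 0.760), and without 30d-7d library 3 the digestive median was -0.16 (adjusted p = 0.248). Without 0d-7d library 3 heat shock proteins had an adjusted p = 0.0805 and without 0d-7d library 2 ribosomal proteins had 0.267. edgeR called 0 unigenes, with 4260 at an unadjusted p under 0.05, and DESeq2 called 333.

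Soil aging by the code at 28 d is 30d-28d against 0d-28d, which the treatment text calls aging at 7 d. Muscle contractile proteins rose with 63 of 88 positive and a median of 0.50 (camera adjusted p = 1.15e-06, and adjusted p = 0.649 with an estimated correlation). Paramyosin contig_46827, of the thick filaments of invertebrate muscle, gave 2.54 (SE 0.569) and myosin contig_592 gave 2.90 (SE 0.886). Lombricine kinase contig_13426, which buffers ATP in earthworm muscle, gave 2.72 (SE 0.592), with 824.9 ± 513.2 against 127.4 ± 47.7 FPKM (SD, n = 3). The paramyosin and the lombricine kinase were chosen for their low p in this contrast. All of these unigenes had an edgeR adjusted p = 0.775. Germ cell and sperm proteins fell with 13 of 64 positive and a median of -0.90 (camera adjusted p = 1.86e-05, and adjusted p = 0.729 with an estimated correlation), and the adjusted p was 0.0510 without 0d-28d library 3. Cytosolic ribosomal proteins rose with 40 of 45 positive (camera adjusted p = 0.0227) and ABC transporters, which pump compounds out of cells, with 18 of 23 (adjusted p = 0.0146), and proteasome and ubiquitin proteins fell with 59 of 165 positive (adjusted p = 0.0371). With an estimated correlation these had adjusted p = 0.868, 0.729 and 0.868. At the preset correlation ribosomal proteins had 0.0620 without 0d-28d library 1, and without 0d-28d library 3 ABC transporters had 0.128, proteasome proteins 0.977 and globins 0.0637. Glycolysis and TCA cycle enzymes passed upward (camera adjusted p = 0.00310, and 0.729 as the adjusted p with an estimated correlation) at a median of 0.30 and a mean of -0.09, and globins passed upward (adjusted p = 0.00884, and 0.868) at a median of -0.10 and a mean of 0.09, so that median, mean and test differed in sign. Without 0d-28d library 2 glycolysis had an adjusted p = 0.141. edgeR called 0 unigenes, with 6354 at an unadjusted p under 0.05, and DESeq2 called 592.

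Exposure duration by the code in fresh soil is 0d-28d against 0d-7d, which the treatment text calls 7 d against 0 d. Germ cell and sperm proteins rose with 57 of 64 positive and a median of 1.47 (camera adjusted p = 1.42e-08, and adjusted p = 0.649 with an estimated correlation), and the median was 0.67 without 0d-28d library 3. Globins fell with 2 of 23 positive and a median of -0.85 (camera adjusted p = 1.86e-05, and adjusted p = 0.868 with an estimated correlation), and the adjusted p was 0.588 without 0d-28d library 3. Neurotransmission proteins, digestive enzymes and proteasome and ubiquitin proteins rose by medians of 0.57, 0.85 and 0.46 (camera adjusted p = 0.00510, 0.00903 and 0.0146). Muscle contractile proteins and glycolysis and TCA cycle enzymes fell with medians of -0.38 and -0.50 (camera adjusted p = 0.0119 for each), and respiratory chain proteins passed downward (adjusted p = 0.0421) at a median of -0.47 and a mean of 0.38. With an estimated correlation neurotransmission had an adjusted p = 0.649 and each of the other 5 lists 0.868. The highest preset adjusted p without 1 library was 0.0812 for neurotransmission and 0.410 for the respiratory chain (0d-7d library 3), 0.304 for digestive enzymes (0d-28d library 1), 0.632 for proteasome proteins (0d-28d library 3), and 0.202 for muscle and 0.182 for glycolysis (0d-28d library 2). A kainate-type glutamate receptor (contig_160545) with 2.50 (SE 0.508) and an estrogen receptor match (contig_115639) with 3.02 (SE 0.708) passed when adjusted over the list alone (edgeR adjusted p = 0.0268 and 0.0259), and over all unigenes each had an adjusted p = 0.528. edgeR called 0 unigenes, with 9193 at an unadjusted p under 0.05, DESeq2 called 930, and 11.1% of unigenes did not overlap where chance gives 10%.

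Exposure duration by the code in aged soil is 30d-28d against 30d-7d. Neurotransmission proteins rose with 58 of 85 positive and a median of 0.36 (camera adjusted p = 0.00664) and muscle contractile proteins with 61 of 88 and 0.36 (adjusted p = 0.0137). With an estimated correlation these had adjusted p = 0.729 and 0.868, and without 30d-28d library 2 the muscle list had 0.465 at the preset correlation. The pedal peptide neuropeptide contig_3095 gave 0.20 (SE 0.823). Glycerol-3-phosphate dehydrogenase contig_1774, which links glycolysis to lipid synthesis and was chosen for its low p, gave 1.86 (SE 0.465). A DnaJ-like chaperone (contig_108214) gave -8.13 (SE 1.97) and passed when adjusted over the list alone (edgeR adjusted p = 0.0474) but not over all unigenes (adjusted p = 1). It had 0 to 0.074 FPKM in the 30d-28d libraries. Low values also came in control library 2 (0.063), 0d-7d library 2 (0.466) and 0d-28d library 3 (0.718). The remaining libraries had 6.23 to 17.7 FPKM. edgeR called 0 unigenes, with 3123 at an unadjusted p under 0.05, and DESeq2 called 324.

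The remaining contrasts change both soil aging and exposure under the code. Under the treatment text 30d-28d against 0d-7d is 7 d in aged soil against 0 d. That text gives the 0 d worms no soil aging, so lindane, time in the soil and soil aging cannot be told apart there. By the same text 30d-7d against 0d-28d is 28 d against 7 d in fresh soil, a change of exposure duration alone. In 30d-28d against 0d-7d, cathepsin C contig_650 gave 1.48 (SE 0.313) and cathepsin L contig_3410 gave 1.98 (SE 0.423), each with an edgeR adjusted p = 0.885. In 30d-7d against 0d-28d, stabilin-2 contig_1679, a scavenger receptor, gave -2.24 (SE 0.504) and an inhibitor of apoptosis protein contig_134546 gave 1.72 (SE 0.366), each with an edgeR adjusted p = 0.789. edgeR called 0 unigenes in both, with 5382 and 6350 at an unadjusted p under 0.05, and DESeq2 called 415 and 560. For the interaction of aging with duration edgeR also called 0, with 5656 at an unadjusted p under 0.05, and DESeq2 called 493. Taking the libraries coded 0d-7d as worms at 0 d, the triplets coded 0d-28d, 30d-7d and 30d-28d had 0 unigenes changed against them by edgeR (9193, 4260 and 5382 at an unadjusted p under 0.05, and 930, 333 and 415 called by DESeq2), and the triplet coded control had contig_17698. Under that text contig_17698 would be higher after 28 d in aged soil than in each other condition.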

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

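The interaction tests and the fits without 1 library were planned before the data were examined, and the glycolysis members named were chosen after their values were seen. For 4 gene lists the interaction of coded aging and exposure passed in camera at the preset correlation, a test of the difference itself, and passed for none of them with an estimated correlation or in fry. Muscle contractile proteins gave an adjusted p = 7.06e-05 with 63 of 88 unigenes positive and a median of 0.66, and glycolysis and TCA cycle enzymes 0.00529 with 43 of 66 and 0.51. Globins gave 0.0215 with 16 of 23 and 0.24. Germ cell and sperm proteins gave 2.39e-07 with 9 of 64 positive and a median of -1.25. With an estimated correlation the adjusted p was 0.461 for muscle and germ cell proteins, 0.494 for glycolysis and 0.701 for globins. In fry it was 0.424, 0.424, 0.495 and 0.705 for muscle, germ cell, glycolysis and globins.

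Within glycolysis, 6 members passed when adjusted over the list alone, with L-lactate dehydrogenase contig_31352 at 4.26 (SE 1.17), phosphofructokinase contig_133231 at 3.87 (SE 0.934) and glyceraldehyde-3-phosphate dehydrogenase contig_33542 at 5.23 (SE 1.20). Over all unigenes each had an edgeR adjusted p = 0.868. The phosphofructokinase had 21.3 FPKM in 0d-7d library 3 and 29.7 FPKM in 30d-28d library 2, the 2 highest of the 15 libraries.

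Leaving out 0d-28d library 3 moved the globin median to -0.29 (adjusted p = 0.630) and the germ cell median to -0.54 (adjusted p = 0.00169). Over 12 fits without 1 library of the 4 triplets, the list passed in 12 for muscle and germ cell proteins, 9 for glycolysis (highest adjusted p = 0.128, without 30d-7d library 1) and 6 for globins. Globins took 0.00322% of the reads of 0d-28d library 3 and at least 0.301% in each other library, and germ cell proteins 0.572% there and at most 0.0897% elsewhere. Under the treatment text the 4 triplets would not form this interaction. No biological explanation was tested for these lists.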

How the results depend on the processing

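The settings chosen after the results were seen were limma on log2(FPKM + 1), FPKM of at least 1 in 3 libraries, 2 to 4 surrogate variables, reads summed by matched protein and DESeq2 on random splits. For each change below the cause was not tested unless one is given.

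contig_17698 was lower than control in each of the 11 other settings for which its change was computed, by -5.60 to -2.95 on the log2 scale over the 4 comparisons. The counts stayed within 1.5 times with DESeq2 size factors in place of TMM and a minimum log2 change of 1. In what follows the 4 comparisons with control are in the order 0d-7d, 0d-28d, 30d-7d and 30d-28d.

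Without a filter 0d-7d and 30d-28d had 2, and the test of any difference 2. At a mean of at least 5 FPKM all 4 had 0, the test of any difference 0 and the same way in all 4 comparisons 0, since contig_17698 was removed. At FPKM of at least 1 in 3 libraries any difference had 2. Fitting only the libraries compared gave 0 in each of the 4, 0 the same way in all 4 and 1 for 30d-28d against 0d-7d. The replicate block gave 0 for 0d-7d and 0 the same way in all 4. Replicate numbers did not pair libraries (mean correlation of deviations -0.058, over 0.1 in 3 of 30 pairs).

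Named from the treatment field, 0d-7d, 0d-28d and 30d-7d against control had 0 and the same way in all 4 had 0. It gave 1 for 30d-28d against 0d-28d, against 0d-7d and against 30d-7d, and 1 for the interaction, because the names move by one triplet.

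DESeq2 called 336, 912, 316 and 408 against control, 333 for 30d-7d against 0d-7d, 592 for 30d-28d against 0d-28d, 930 for 0d-28d against 0d-7d, 324 for 30d-28d against 30d-7d, 415 for 30d-28d against 0d-7d, 560 for 30d-7d against 0d-28d, 493 for the interaction, 1042 for any difference and 58 the same way in all 4. Over 10 contrasts it called 5126, and on 11 random splits 4193 to 22407, with 9 of them at least as many, so these calls do not separate the real triplets from random ones.

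limma on log2(FPKM + 1) and with TMM-type factors gave 4, 4, 3 and 3 against control, and 1 each for 0d-28d against 0d-7d, 30d-28d against 0d-28d and 30d-7d against 0d-28d. Any difference had 6 and 5, and 3 went the same way in all 4. Quantiles and no trend gave 4, 4, 3 and 3, 1 for 0d-28d against 0d-7d, 5 for any difference and 3 the same way. Array weights gave 5, 4, 3 and 3, 3 for 0d-28d against 0d-7d, 1 for 30d-28d against 0d-28d, 1 for 30d-7d against 0d-28d, 5 for any difference and 3 the same way. log2(FPKM + 0.1) gave 3, 0, 0 and 0, and 0 the same way. Besides contig_17698, limma on log2(FPKM + 1) called contig_170000 and contig_212370, lower in all 4. It also called contig_15794 higher in 0d-7d (adjusted p = 0.00735) and contig_50799 higher in 0d-28d (adjusted p = 0.0226). Against edgeR, log2(FPKM + 0.1) moved the median log2 change of all genes by 0.12 in 30d-7d against 0d-28d, from -0.05 to 0.07, and by under 0.1 in the 10 other contrasts, as did log2(FPKM + 1), TMM-type factors and quantiles in all 11.

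With 2 surrogate variables 0d-7d, 0d-28d and 30d-7d had 3, 2 and 2, 30d-7d against 0d-7d 3, 0d-28d against 0d-7d 2, 30d-28d against 0d-28d 1, 30d-28d against 0d-7d 1, 30d-7d against 0d-28d 2, the interaction 1 and any difference 7. With 3, 0d-7d and 0d-28d had 0, any difference 0 and the same way 0. With 4, and with reads summed by protein, all 4 had 0, any difference 0 and the same way 0. Summing leaves out contig_17698, which has no protein match.

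The 43 gene list calls became 0 with an estimated correlation and 0 in fry. Other settings gave 33 to 39.

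Leaving out 1 library in turn gave 0 to 2, 0 to 3, 0 to 1 and 0 to 2 against control. For 30d-7d against 0d-7d it gave 0 to 1, 30d-28d against 0d-28d 0 to 2, 0d-28d against 0d-7d 0 to 1, 30d-28d against 30d-7d 0 to 0, 30d-28d against 0d-7d 0 to 1 and 30d-7d against 0d-28d 0 to 2. The interaction had 0 to 0, any difference 1 to 3, the same way in all 4 had 0 to 1 (moved in 13 of 15) and list calls 30 to 45. No called value changed sign, and uncalled named unigenes did in 69 of 1158 such values and 3 of 193 with the replicate block. On simulated counts edgeR recovered 6 of 67 changes of 16 fold and 31 of 66 of 64 fold, so most changes of either size were missed.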

Other observations

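Tests chosen after the result was seen were the ND2 test, the ND4 test by triplet, the triplet and body-part tests of library distances, and both tests of the long unigenes. The choice of these patterns, in place of the unigenes high in control, also came after their results were seen.

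Random groupings of the 15 libraries into 5 triplets were compared with the real one, 40 in all. For 1 unigene changed the same way in all 4 comparisons with control, 1 of 40 groupings gave as many. It was the real one (highest other 0), a share under 0.05 that by this test alone argues against chance. The count is contig_17698 alone, and it moved in 13 of 15 fits without 1 library (0 to 1). In fits without 1 of the libraries compared the log2 change of contig_17698 was -5.60 to -3.90, so the call was lost while the change stayed large. Of 455 sets of 3 libraries, 56 (12.3%) had at least as many unigenes high in them as control. Chance therefore stays open for the count and for contig_17698. For any difference 15 of 40 gave as many as the real 1 (highest other 3), for the interaction 40 of 40 as many as the real 0 (highest other 2), and for gene lists 7 of 40 as many as the real 43 (highest other 50, median 32), so chance is not excluded for these. In 8 simulations of unchanged triplets the lists gave 0 calls, which leaves the correlation of list members across libraries as a candidate source of the 43.

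With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. As many as the real count came in 1 for 0d-7d against control (real 1, highest other 0), 2 for 0d-28d (1, 1), 5 for 30d-7d (1, 2) and 5 for 30d-28d (1, 2). In each of the other 6 contrasts the real count was 0, so that all 10 had as many. The highest other count was 1 for 30d-7d against 0d-7d, 3 for 30d-28d against 0d-28d, 1 for 0d-28d against 0d-7d, 2 for 30d-28d against 30d-7d, 1 for 30d-28d against 0d-7d and 1 for 30d-7d against 0d-28d.

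Libraries resembled libraries of other triplets more than their own. Differences in depth were to go with the distances, and did not (Mantel r -0.02, permutation p = 0.510). The power of this test is not known, so depth stays open. A lindane condition acting alike on the libraries of a triplet would make them more alike, and they were not (permutation p = 0.984). That value and the other tail of the test (share 0.0164) both restate the pattern. They show no likeness that follows the triplets, but do not decide on lindane as the source. Body parts sampled within a triplet also stay open. Tissue lists were more correlated across libraries than random lists in 5 of 5, but so were 23 of 23 lists, so tissue content stays open. Before all lists were compared, 5 of 5 had been read as support, and that reading was withdrawn.

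The dominant mitochondrial ND4 unigene, contig_60, contig_149 or contig_89, was shared by the 3 libraries in 0 of 5 triplets. The dominant unigene thus did not follow the triplets. That count restates the pattern and is no separate test of lindane as the source. contig_60 varied 2564 fold across libraries while ND4 over ND1 varied 1.95 fold. Mitochondrial variants of different animals were to show in ND1, and did not (Mantel permutation p = 0.661). They did go with ND2 over ND1 (Mantel r 0.36, permutation p = 0.00438), so that variants remain a candidate explanation on the second test only. Library pairs that differed in ND4 make-up did not differ more in which other unigenes were present (Mantel r -0.03, permutation p = 0.576). The power of this test is not known, so separate lineages, with nuclear unigenes included, stay open.

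There were 29 unigenes over 50000 bases, 3454261 bases in all, 23 of them with a best match in *Trichuris trichiura*, and they took 0.120% to 0.560% of the reads. Within a library their reads per base differed by at most 1.44 fold, against 628 fold (95th over 5th percentile) for 1544 shorter unigenes. The unigenes with elongation factor Tu or ribosomal proteins stood at most 1.05 times the median. The values of the long unigenes restate their even level and were seen first, so they are no support for DNA of a bacterial genome. Transcripts of a living bacterium would differ in level between genes. Each unigene averages many genes, which narrows such differences. Even so, all 29 lay within 1.44 fold in each library, which argues against transcripts as the main source of these reads. No explanation by lindane or soil aging was tested. Control libraries held 0.140%, 0.142% and 0.120%, among the 4 lowest with 0d-28d library 3 (0.140%). contig_41956 and contig_55734 are also in the bacterial list that passed against control in 30d-7d and 30d-28d. Against control they gave log2 changes of 0.68 and 0.66 in 30d-7d and 0.36 and 0.43 in 30d-28d. They gave 1.34 and 1.26 in 0d-7d, where the list did not pass. Those list calls share these members with the long unigenes, and how far they rest on them was not tested.

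Unigenes at least 8 times higher in each of 3 libraries than in any other numbered 933, over 455 sets of 3 libraries. The set 30d-7d library 1, 30d-28d library 3 and control library 2 had 224, the next 20, and the 5 triplets together 4, all in control. Destabilase I (First_Contig3267) had 5111, 2704 and 8988 CPM in those 3 libraries and 272 CPM in 0d-7d library 2. The 4 control unigenes were contig_17698, contig_170000, contig_76215 and contig_212370, and 56 of the 455 sets had at least 4. Relative to contig_17698, the other 3 differed in ratio between control libraries by up to 6.50 fold.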
